A study of Mus musculus with 2 samples.

How the data were processed

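Nuclei from the ventral tegmental area (VTA) of mice were profiled with 10x Genomics 3' chemistry in 2 libraries, 1 named WT and 1 named CCI. CCI stands for chronic constriction injury of the sciatic nerve, a model of neuropathic pain in which loose ligatures are tied around the nerve. The labels place the injury on the left and describe the right nerve as exposed without ligature. The labels do not say from which hemisphere tissue was taken, nor how many animals were pooled, and there are no replicate libraries. The series design speaks of nuclei while the protocol describes an enzymatic tissue digestion; barcodes are called nuclei here.

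The deposited matrices hold UMI counts per gene and barcode, which the authors made with Cell Ranger (7.1.0 in the file headers) on build mm10. Seurat is also named per the labels, with no settings, and the annotation release and the use of intronic reads are not stated. All entries were whole numbers. No barcode held fewer than 462 UMIs in the WT library or 500 in the CCI library, so empty droplets had been removed beforehand. Of the 32285 gene identifiers, 32158 (99.6%) were in the GENCODE vM21 annotation, which gave the coordinates. Genes whose exons overlap a gene on the other strand are named as such, because the strand setting of the counting is not stated.

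A barcode was kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrially encoded UMIs. Scrublet, as included in Scanpy 1.11.5, was run within each library at an expected doublet rate of 10% and called 1233 WT barcodes (9.19%) and 967 CCI barcodes (7.04%) as doublets, which were removed. Counts were log-normalized and each gene was scaled within its library. The 2000 most variable genes gave 30 principal components (NumPy 2.4.6), a graph of 20 nearest neighbours (scikit-learn 1.9.0) and Leiden clusters at a resolution of 1.0 (leidenalg 0.10.2). Nuclei of the neuron class were clustered again in the same way.

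A cluster took the name of the class with the highest mean relative level of its markers, where a marker's level was its CPM divided by the highest CPM in any cluster plus 50. The name required a level of at least 0.25, at least 1.5 times the next class, at least 3 markers detected in 5% of the nuclei, at least 20 nuclei, and no more markers of another class than of its own among the 10 leading genes. A shallow cluster without a marker of its class among them stayed unnamed. The markers of 24 classes were fixed before the data were examined. The naming rule itself was set in 3 versions after the cluster tables had been seen, with a level of 0.3, 0.2 and then 0.25, and with leading genes taken first against all other clusters and then against clusters of other classes. Its other versions are among the alternatives, and the share of GABAergic neurons depended on them.

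UMI counts were summed per library and class and expressed as CPM, the counts scaled to a common total. Ratios are log2 of CCI over WT with an exact conditional 95% interval (SciPy 1.17.1), and shares carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only. With 1 library per group no test between the groups was possible, so a difference describes these libraries. A gene at 0 in 1 library was set against a floor of 3 counts. For a list of genes, the median ratio of the members with at least 20 UMIs in the class was placed among 10000 random lists of the same size matched in 20 bins of mean expression. That percentile is a description and not a test. For shares of nuclei with a UMI, every nucleus was thinned to 1000 UMIs and shallower nuclei were left out.

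The comparisons, the cell filters, the 31 gene lists, the rule for naming genes and most of the other settings below were fixed before the data were examined. Within a class the rule took genes with at least 100 UMIs over both libraries, excluding mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes, unnamed gene models, markers of other classes, and genes whose CPM in the class, in the library where it was higher, lay below that over all kept nuclei. Genes were ranked by the interval bound nearest to 0, and the 10 highest and 10 lowest were taken in astrocytes, dopaminergic and GABAergic neurons, and the 5 highest and 5 lowest in other classes, with up to 4 members of each list described and a fixed set of marker and transmitter genes. A few genes that the rule names are not reported here. Classes with at least 50 nuclei in both libraries were compared. The lists and fixed genes described in each class were chosen for their bearing on that class after their values had been seen. The least number of 50 nuclei was applied to the alternatives after a first run.

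Other settings fixed beforehand were stricter filters (500 genes, 10% mitochondrial UMIs), no doublet removal, Leiden resolutions of 0.5 and 2.0, each library clustered alone, clustering without scaling within a library, scaling by the trimmed mean of M values (TMM), a total without mitochondrial, ribosomal protein and haemoglobin genes and Malat1, equal weight per nucleus, thinning, other minimum counts for list members, and neurons gated by at least 2 UMIs of transmitter genes. Marker levels of 0.2 and 0.15, leading genes against all other clusters, equal weight for each cluster shared by the libraries, and that weighting for Sst without subcluster 33 were added after seeing the data. Interval coverage was computed on simulated Poisson counts drawn from a profile pooled over the libraries. The intervals covered 96.1% of the simulated ratios in astrocytes, 96.0% in dopaminergic neurons and 95.7% in GABAergic neurons. For 2-fold changes, 94.0%, 100.0% and 97.0% of the genes that held one were recovered. The interval assumes such counts, so this coverage was given by the setting and says nothing about variation between nuclei or libraries.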

Results

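The WT library held 14114 barcodes with 18581333 UMIs in all, and the CCI library 13736 barcodes with 68376220 UMIs. The median barcode had 975 UMIs in WT and 3652 in CCI, and the median share of mitochondrially encoded UMIs was 0.281% and 0.140%. After filtering, 12191 WT and 12769 CCI nuclei remained, with median depths of 975 and 3456 UMIs. The series title concerns astrocytes, somatostatin GABAergic neurons and dopaminergic neurons of the VTA in neuropathic pain with depression, so expression in these classes was compared between the libraries in turn.

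Composition was compared to show which cells each library held. Dopaminergic neurons, recognised by the dopamine transporter and other dopaminergic markers, were the main neuronal class with a lower share in the CCI library. They made up 844 of 5974 WT neurons (14.1%, 13.25 to 15.04) and 365 of 6613 CCI neurons (5.52%, 4.98 to 6.10), a share 2.56-fold lower. Oligodendrocyte precursors were 4.46% of WT and 2.97% of CCI nuclei. Committed precursors, the stage just before myelination, were 210 WT nuclei (1.72%) and 22 CCI nuclei (0.172%). Microglia were higher in the CCI library, at 1.37% (1.17 to 1.59) in WT and 2.87% (2.58 to 3.17) in CCI. The WT microglia had a median of 554 UMIs, near the least number of 500. That filter removed 690 WT barcodes and 0 CCI barcodes, so the WT share may be lowered by it.

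Neurons were 49.0% of WT and 51.8% of CCI nuclei, oligodendrocytes 31.9% and 28.9%, and astrocytes 10.6% and 11.6%. GABAergic neurons were 15.6% of WT and 17.7% of CCI neurons, a log2 ratio of 0.18 whose direction turned to -0.31 when the marker level for naming a subcluster was 0.15 and reached 1.84 when neurons were gated by transcripts. Most neurons, 70.0% in WT and 76.0% in CCI, lay in subclusters without a transmitter name. Of these, 5 subclusters highest for GABAergic markers held 43.2% of WT and 29.3% of CCI neurons, and 12 subclusters highest for glutamatergic markers held 22.2% and 38.2%. A further subcluster led by Slc6a3 but under the marker level, with 106 WT and 150 CCI nuclei, also held the myelin gene Mbp among its leading genes. With a filter of at least 500 genes, which removes more of the shallow WT library, the ratios turned to -0.20 for neurons and 0.29 for oligodendrocytes, and that for microglia reached 2.52 with 49 WT nuclei. Neurons gated by at least 2 UMIs of Th, Slc6a3, Slc18a2 and Ddc were 15.7% in WT and 14.97% in CCI, a ratio of -0.07, and 84.0% of the gated WT neurons and 36.7% of the gated CCI neurons lay in the dopaminergic class.

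**Figure D1:**
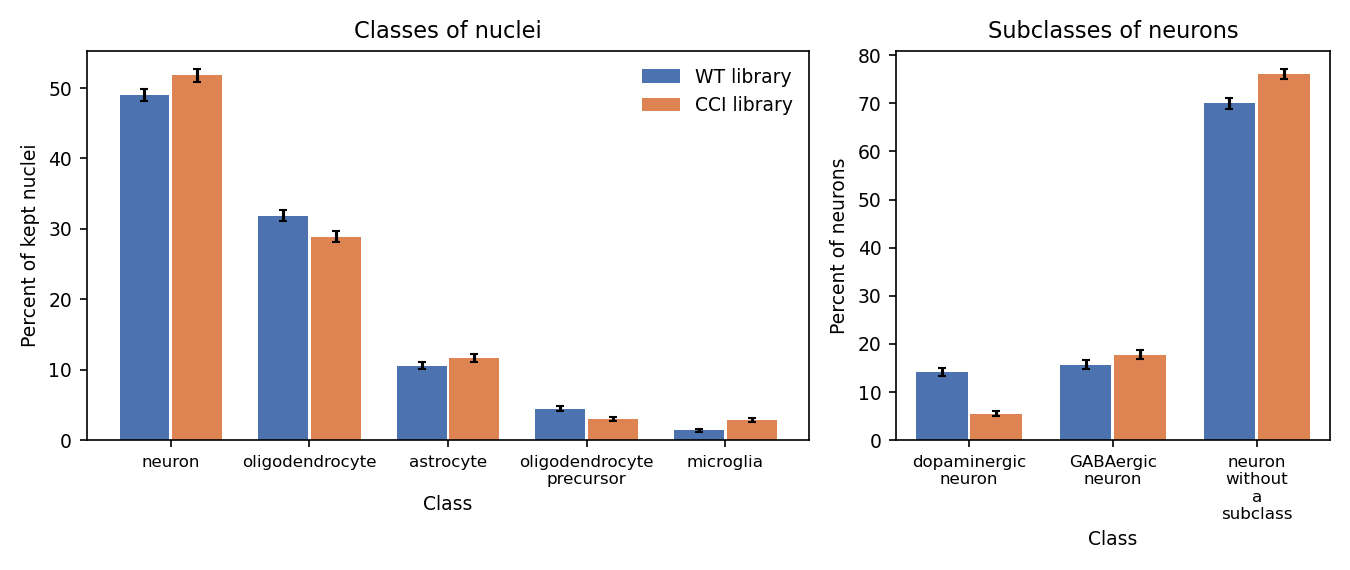
Share of kept nuclei per class (left) and share of neurons per subclass (right) in percent, for the WT and CCI libraries, with bars for 95% Clopper-Pearson intervals. Dopaminergic neurons were 14.1% of WT and 5.52% of CCI neurons, while astrocytes were 10.6% and 11.6% of nuclei.

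The libraries separated within most classes. Of the CCI astrocytes 94.5% lay in a cluster of 108 WT and 1400 CCI nuclei, and of the WT astrocytes 90.1% lay in a cluster of 1161 WT and 81 CCI nuclei. Dopaminergic neurons fell into subclusters of 519 WT and 16 CCI, 325 WT and 100 CCI, and 0 WT and 249 CCI nuclei. Oligodendrocyte precursors split into a cluster of 539 WT and 21 CCI nuclei and another of 5 WT and 358 CCI nuclei. Microglia formed a single cluster of 167 WT and 366 CCI nuclei. A cluster made up mostly of 1 library may stand for that library and not for a cell type.

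Myelin and mitochondrially encoded transcripts were lower in the CCI library in every class, and they stand beside each gene group below. Summed neuronal transcripts stood at -0.12 in astrocytes and 0.16 in oligodendrocytes. Summed astrocyte transcripts stood at 0.02 in oligodendrocytes and 0.43 in GABAergic neurons. The list of myelin genes had a median log2 ratio, CCI over WT, of -1.38 in astrocytes, -1.52 in dopaminergic neurons, -1.03 in GABAergic neurons and -1.02 in microglia. In oligodendrocytes themselves the median was -0.11. Mitochondrially encoded transcripts were lower in all classes, from -0.35 in oligodendrocyte precursors to -1.51 in GABAergic neurons. Dopaminergic transcripts in astrocytes were lower too, with Slc6a3 at 57.2 CPM in WT and 16.2 CPM in CCI.

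In astrocytes, transcripts for complement C4, apolipoprotein E and the glutamate transporter GLAST were higher in the CCI library, and genes induced by glucocorticoids were lower as a group. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, build mm10), which encodes the main lipid carrier that astrocytes secrete, stood at 589.6 CPM in WT and 1396 CPM in CCI, a log2 ratio of 1.24 (1.12 to 1.37) from 608 and 5248 UMIs. C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882), a complement component, had the highest ratio among genes with at least 100 UMIs, 3.06 (1.81 to 4.70), but from 5 UMIs in WT and 152 in CCI. Slc1a3 (ENSMUSG00000005360, chromosome 15, 8634124 to 8710764), which clears glutamate from the synaptic cleft, was 2.00-fold higher, from 727 to 1458 CPM. The other astrocytic glutamate transporter, Slc1a2, was nearly level at 0.20 (0.14 to 0.26), as were the water channel gene Aqp4 (0.08), the glutamine synthetase gene Glul (-0.03) and the connexin gene Gja1 (0.02).

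Among the other genes ranked highest by the interval bound nearest to 0 were Itih3, an extracellular matrix protein gene (1.41), the imprinted gene Nnat (1.48), the AMPA receptor subunit gene Gria1 (0.96), Ttll3 (1.99), Galnt16 (1.39), the interferon-inducible Ifi27 (1.89) and Adam11 (1.56). Ranked lowest were Igfbp2, which encodes a binding protein of insulin-like growth factors (-1.76), the small GTPase gene Rhob (-1.60), Stk32a (-1.28), Usp53 (-1.07), Pcyox1l (-1.47), Smim3 (-1.14), the RNA-binding protein gene Pcbp1 (-1.16), the receptor phosphatase gene Ptprj (-0.77) and Zbtb16 (-0.84). AY036118, whose exons overlap the other strand of Gm42418, was also lower (-0.76). Exons of Ttll3 overlap Arpc4 on its own strand, and those of Galnt16 overlap models on the other strand.

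Glucocorticoid-responsive genes had a median ratio of -0.52 in astrocytes (-0.73 to -0.23), at percentile 0.01 of matched random lists. None of the 14 measured members was over 1.5-fold higher and 6 were over 1.5-fold lower, among them the transcription factor gene Zbtb16, the kinase gene Sgk1 (-0.97), and the glucocorticoid receptor co-chaperone gene Fkbp5 (-0.88), while Tsc22d3 stood at -0.56. Immediate early genes had a median of -0.60 over 7 measured members, with Junb at -1.73 from 10 and 11 UMIs. Of the A1-type reactive genes only 4 of 11 were measured, with a median of 1.19 (0.46 to 2.18) at percentile 99.96: Ggta1 at 2.504 (0.89 to 4.82), Fbln5 at 1.57, the MHC class I gene H2-D1 at 0.81 and Fkbp5. The pan-reactive genes had a median of 0.37 over 4 measured members, led by the intermediate filament gene Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912) at 2.10 (0.81 to 3.76) from 5 and 78 UMIs.

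The groups tied to transmitter handling were close to level. The 18 genes for transmitter and potassium clearance had a median of 0.05 at percentile 84.5, with 2 over 1.5-fold higher (Slc1a3 and Glud1, glutamate dehydrogenase, at 0.72) and 16 within 1.5-fold. Synapse-organizing factors had a median of -0.09 at percentile 15.5, with Ephb1 at -0.87, the neurotrophin gene Bdnf at -1.15 from 28 and 46 UMIs, and Efnb3 at -1.03. Receptor and calcium signalling genes had a median of 0.13, with the GABA-B receptor gene Gabbr2 at 0.59, the endothelin receptor gene Ednrb at 0.68 and the glutamate receptor gene Grm3 at 0.51. Cholesterol synthesis genes had a median of -0.11 (percentile 9.91), with Hmgcs1 at -0.60 and Msmo1 at -0.43, MHC class I genes one of 0.15 (52.7), with Nlrc5 at 1.55 and H2-K1 at 0.09, and ribosomal protein genes one of 0.33 (99.8), with Rpl41 at 1.76 and Rpl19 at 1.17. Sparcl1 and Aldoc, genes abundant in astrocytes, were at 0.34 and 0.34. Beside these groups, the myelin genes had a median of -1.38, with Mbp at -1.56, the mitochondrially encoded genes one of -0.48, with mt-Nd6 at -1.41 and mt-Nd3 at -1.09, and the dopamine genes one of -0.63, with Slc6a3 at -1.82 and Slc18a2 at -1.61.

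Thinning to 1000 UMIs left 207 of 1289 WT astrocytes against 1469 of 1481 CCI astrocytes and brought the ratios of Jund to 0.17 (-1.55 to 2.55, from 3 WT UMIs) and of Slc7a11 to -0.03, and moved Nnat to 2.37, Adam11 to 3.66 (1.15 to 8.98, from 1 WT UMI), Igfbp2 to -2.63 and Pcbp1 to -0.43. C4b, Gfap and Ggta1 then had no WT UMI against 63, 26 and 31 in CCI, so thinning leaves only bounds, of at least 1.57, 0.29 and 0.54, and the A1-type list, with Ggta1 at its bound, stood at 0.07. The pan-reactive list, with 2 of its 4 members at the floor, stood at -0.71, and the MHC class I list, with 3 of 8 there, at -0.39. Nlrc5, with 0 WT and 11 CCI UMIs, gave no direction. With equal weight for the pair of astrocyte clusters, Itih3 stood at 0.57, Ggta1 at 6.12 (from 1 WT UMI), Slc6a3 at -2.96, Stk32a at -0.69, Slc1a2 at -0.17, Slc7a11 at -0.37 and H2-K1 at -0.77, Fkbp5 turned to 0.08, Ephb1 to 0.10, Mbp to 0.12 and mt-Nd6 to 0.25, and the list medians turned to 0.00 for myelin, 1.04 for mitochondrially encoded genes and -0.15 for clearance genes.

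**Figure D2:**
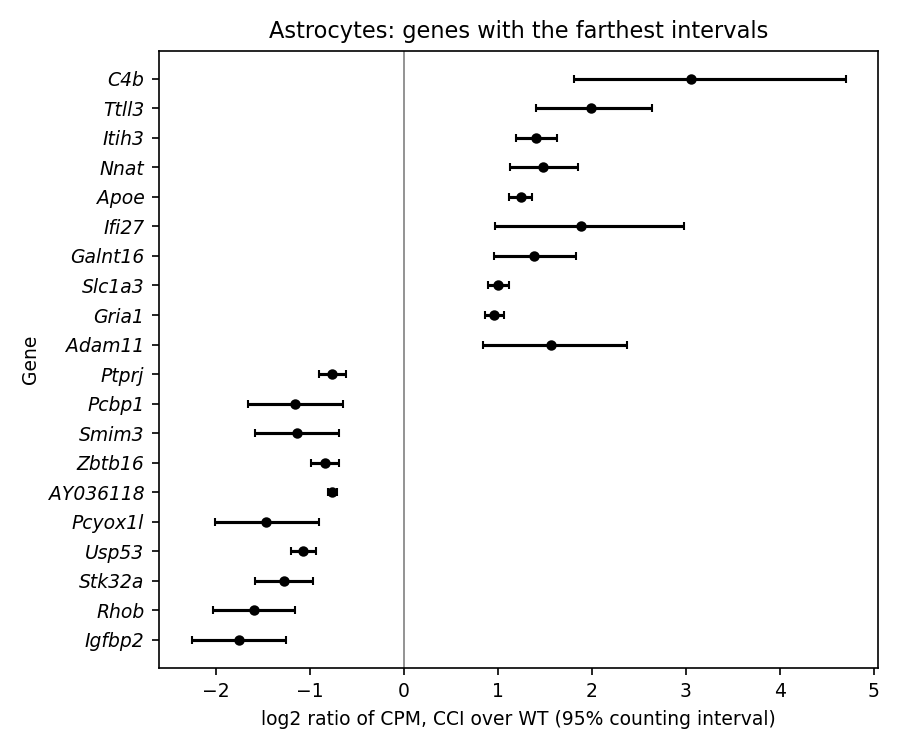
Log2 ratio of CPM, CCI over WT, in astrocytes for the 10 highest and 10 lowest genes ranked by the interval bound nearest to 0, with bars for 95% counting intervals. C4b had the highest ratio, 3.06, and Igfbp2 the lowest, -1.76.

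In the nuclei named dopaminergic neurons, most genes for making, loading and reclaiming dopamine had similar levels in both libraries. The class was named by its level of such markers, so nuclei with lower levels may fall outside it and the similarity is partly given by the naming. Th (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128), the rate-limiting enzyme of dopamine synthesis, stood at 163 CPM in each library (ratio 0.00, -0.20 to 0.20), from 321 and 588 UMIs. The dopamine transporter gene Slc6a3 (ENSMUSG00000021609, chromosome 13, 73536747 to 73578672) stood at 652 and 651 CPM (0.00, -0.10 to 0.10), and the decarboxylase gene Ddc at 0.14 (0.05 to 0.23). The vesicular monoamine transporter gene Slc18a2, whose exons overlap Gm29261 on the other strand, was lower at -0.39 (-0.46 to -0.32), from 1358 to 1037 CPM. The 20 measured genes for dopamine synthesis, transport and identity had a median of 0.00 (-0.12 to 0.09) at percentile 49.3, with 18 within 1.5-fold and 2 lower, En2 (-0.76) and Qdpr (-0.72), and with the transcription factor gene Nr4a2 at -0.28.

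Ranked highest in dopaminergic neurons were Vwa5b1 (2.03, 1.36 to 2.79, from 20 and 150 UMIs), Otx2os1 (1.42), which overlaps the other strand of Otx2, the sugar transporter gene Slc50a1 (1.39), Arhgef33 (1.38), Donson (1.34), the integrin gene Itga11 (1.33), the mitochondrial ribosome gene Mrps26 (1.20), Izumo4 (1.12), Smg5 (1.10), which acts in nonsense-mediated decay, and Mid1 (0.96). Ranked lowest were AC160336.1 (-1.91), Fam129a (-1.30), Papss2 (-1.21), the proline dehydrogenase gene Prodh (-1.15), the pacemaker channel gene Hcn3 (-1.08), Srrm4os (-1.08), Atxn2l (-0.95), the Wnt receptor gene Ror2 (-0.86), and the abundant Cadm2, a synaptic adhesion molecule gene, from 7409 to 4926 CPM (-0.59, -0.62 to -0.56), and Elavl2, a neuronal RNA-binding protein gene, from 1088 to 728 CPM (-0.58). Exons of Arhgef33, Donson, Mrps26, Mid1, AC160336.1, Srrm4os, Cadm2 and Hcn3 overlap other genes.

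Receptor genes in the dopaminergic class were near level, though not in neurons gated by transcripts. GABA receptor subunits had a median of 0.07 (percentile 86.2) over 14 measured genes, with Gabra2 at 0.42 and Gabrb1 at 0.22, and ionotropic glutamate receptor subunits one of 0.02 (76.6) over 17, with Grin2a at 0.31, Grin3a at 0.44 and Gria1 at 0.26. Neuropeptide and opioid receptor genes had a median of 0.19 over 5 measured members, with Oprk1, the kappa opioid receptor, at 0.18 and Cck at 0.19. The medians were -0.05 for immediate early genes, with Dusp1 at -1.41 and Junb at -0.76, -0.07 for heat shock genes, with Hsph1 at -0.84 and Dnajb1 at -1.36, and -0.13 for glucocorticoid-responsive genes, with Tsc22d3 at -1.04 and Zbtb16 at -0.32. Beside them, myelin genes had a median of -1.52, with Cldn11 at -2.23, and mitochondrially encoded genes one of -1.02, with mt-Nd6 at -1.94 and mt-Nd4l at -2.07.

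The gate takes any neuron with 2 UMIs of the dopaminergic genes, so in the deeper CCI library it admits nuclei with lower levels and lowers their ratios by construction. In neurons gated by transcripts the ratios were -1.09 for Slc6a3, -1.004 for Th, -1.18 for Slc18a2, -0.68 for Ddc, -1.64 for En2, -1.02 for Nr4a2 and -0.83 for the dopamine list, those of Grin2a, Oprk1 and Cck turned to -0.09, -0.52 and -0.47, the list medians were 1.09 for neuropeptide and opioid receptor genes, 0.55 for GABA receptor subunits, 0.23 for glutamate receptor subunits and 0.39 for immediate early genes, and the ratios of Gabra2 and Otx2os1 moved to 1.34 and 0.72. In the single subcluster shared by at least 20 nuclei of each library, Slc6a3 stood at -0.61, Th at -0.49, Slc18a2 at -0.64, Grin2a at -0.36, Ddc at -0.12, Tsc22d3 at -0.24, Fam129a at -3.82, AC160336.1 at -3.18, Prodh at -2.24, Hcn3 at -1.77, Ror2 at -1.71 and the myelin list at -0.82, and thinning turned Mid1 to -0.24 and moved Otx2os1 to 0.53, Mrps26 to 0.54 and Slc50a1 to 2.23. Dusp1 had 7 WT UMIs and 0 CCI UMIs after thinning, a ratio of at most -0.17.

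In GABAergic neurons, somatostatin transcripts were higher in the CCI library, together with a larger share of 3 subclusters led by Sst among other genes. Sst (ENSMUSG00000004366, chromosome 16, 23889573 to 23890958), which encodes the inhibitory peptide named in the series title, stood at 36.6 CPM in WT and 94.1 CPM in CCI, a ratio of 1.36 (1.00 to 1.74) from 67 and 771 UMIs. The 3 subclusters with Sst among their leading genes held 96 of 934 WT nuclei (10.3%, 8.41 to 12.4) and 675 of 1170 CCI nuclei (57.7%, 54.8 to 60.5). Leading genes came from the counts of both libraries together, most of them from CCI, which favoured subclusters rich in CCI nuclei. Subcluster 33, with 21 Sst UMIs in 32 WT nuclei, was not in this set, so the split below depends on the pick. Within these subclusters Sst stood at 198 CPM in WT and 152 CPM in CCI, and in the other 8 subclusters at 19.9 and 21.5 CPM. Of the Sst UMIs in these other subclusters, subcluster 33 held 21 of 33 in WT and 10 of 78 in CCI. The similar levels there therefore rest on it. With equal weight for each of the 9 subclusters shared by the libraries the ratio of Sst turned to -1.06 (-1.45 to -0.61). Much of this came from subcluster 33 of 32 WT and 29 CCI nuclei (-2.97, -4.22 to -1.82), and without that subcluster the ratio was -0.34 (-0.80 to 0.19). The weighting left out subclusters 25 (0 WT and 134 CCI nuclei) and 29 (1 and 97). It kept all 67 WT Sst UMIs but 511 of 771 in CCI. Single subclusters went both ways, with subcluster 10 at -0.93 (-1.54 to -0.26), 12 at -0.31 (-1.22 to 0.77) and 8 at 1.96 (0.71 to 3.485), and 24 with 0 WT and 15 CCI UMIs. With each library clustered alone the ratio over all GABAergic neurons was 2.51.

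The share of GABAergic neurons with an Sst UMI, every nucleus thinned to 1000 UMIs, was 3.13% (2.05 to 4.55) in WT and 7.86% (6.39 to 9.56) in CCI, with 102 WT nuclei and no CCI nucleus left out and median depths of 1936 and 6113 UMIs before thinning. Without thinning the shares were 4.07% and 20.7%. In oligodendrocytes, which should lack Sst, the thinned shares were 0.365% and 1.32% at median depths of 1177 and 1947 UMIs, with 3340 and 114 nuclei left out. Over all neurons the thinned shares with Sst were 1.39% and 3.41%, and 2.04% and 9.62% without thinning.

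The somatostatin receptor genes were sparsely counted in GABAergic neurons. Sstr2 (ENSMUSG00000047904, chromosome 11, 113619342 to 113626028) was lower at -0.90 (-1.68 to -0.07) from 20 and 48 UMIs, Sstr1 stood at -0.68 (-1.76 to 0.53) and Sstr3 at 0.42 (-1.35 to 2.83). The list of somatostatin and its receptors had a median of -0.13 over 4 measured genes (percentile 18.0). Genes for GABA synthesis and release were near level, with a median of 0.07 (0.00 to 0.14) over 20 genes at percentile 86.2. Gad1 and Gad2, which encode the GABA-synthesizing enzymes, stood at -0.09 and 0.37, the vesicular transporter gene Slc32a1 at 0.28, the complexin gene Cplx2 at 0.93, Sv2a at 0.34 and the calcium sensor gene Syt1 at 0.16.

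Neuropeptide and opioid receptor genes were higher as a group in the GABAergic neurons of the CCI library, with a median of 0.57 (0.14 to 0.91) at percentile 99.6, and 7 of 15 measured members over 1.5-fold higher against 1 lower. The same list stood at 0.55 (0.29 to 1.02, percentile 98.8) in oligodendrocytes, which should lack these transcripts, with 5 of 12 measured members over 1.5-fold higher and none lower. The enkephalin gene Penk stood at 1.65 from 12 and 169 UMIs (2.66 at the lower and 3.06 at the higher resolution, each from 4 WT UMIs), the galanin gene Gal at 3.26 (0.71 to 8.60) from 1 and 43, Npy at 1.26 from 10 and 107, and the neurotensin gene Nts at 2.23 (0.29 to 5.32) from 2 and 42. Ionotropic glutamate receptor subunits had a median of 0.12 (percentile 96.8), with the kainate receptor genes Grik1 at 1.02, Grik3 at 0.70 and Grik5 at 0.55, and GABA receptor subunits one of 0.06 (73.6), with Gabrg3 at 0.39 and Gabra3 at 0.42. Immediate early genes had a median of 0.02 (16.3). Of them Npas4 stood at 2.74 (0.15 to 8.09) from 1 and 30 UMIs, and Fosl2, with 0 and 30 UMIs, was at least 2.23-fold higher. Glucocorticoid-responsive genes had a median of -0.36 (0.38), with Tsc22d3 at -1.23 and Zbtb16 at -0.48. Beside these groups, myelin genes had a median of -1.03, with Mobp at -1.65, mitochondrially encoded genes one of -1.53, with mt-Nd6 at -2.40 and mt-Atp6 at -1.77, and dopamine genes one of -0.05, with Slc6a3 and Aldh1a1 at -1.58 each.

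Among the genes ranked highest in GABAergic neurons were Pax3, Chrna5, Pdzd2, Eepd1, Ecel1, Meis2 and Ebf2. These lead clusters or subclusters shared unevenly by the libraries, such as 1 of 97 CCI nuclei and 1 WT nucleus. Gata3, Pax5, Bcl11b and Sema3e lead subclusters held mostly by the WT library. The ratios of all these genes are therefore left out of this description. Outside these, Stxbp6 (-1.03), Frs3 (-1.56), Pcyox1l (-1.57) and Atxn2l (-1.13) were lower, while the calcium channel subunit gene Cacna2d3 (1.37), Zbtb7c (1.73) and the transcription factor gene Isl1 (3.32, or 5.08 with each library clustered alone, from 1 WT UMI) were higher. Exons of Frs3 overlap another gene. With equal weight per shared subcluster Stxbp6 stood at -0.22, Frs3 at -0.87, Cacna2d3 at 0.37, Zbtb7c at 0.26, Isl1 at 0.36, Sstr2 at -1.76 and Npy at 0.16, and Grik1 and Grik3 turned to -0.39 and -0.28. In neurons gated by transcripts, with the same effect of depth on the gated genes, Gad1, Gad2 and Slc32a1 stood at -1.15, -0.98 and -0.83, the release list at -0.01, the immediate early list at -0.29 and Aldh1a1 at -0.62, and thinning moved Tsc22d3 to -0.60, Aldh1a1 to -2.26 and mt-Nd6 to -3.15 and left Npas4 and Fosl2 with no WT UMI and 4 CCI UMIs each, too few for a ratio.

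**Figure D3:**
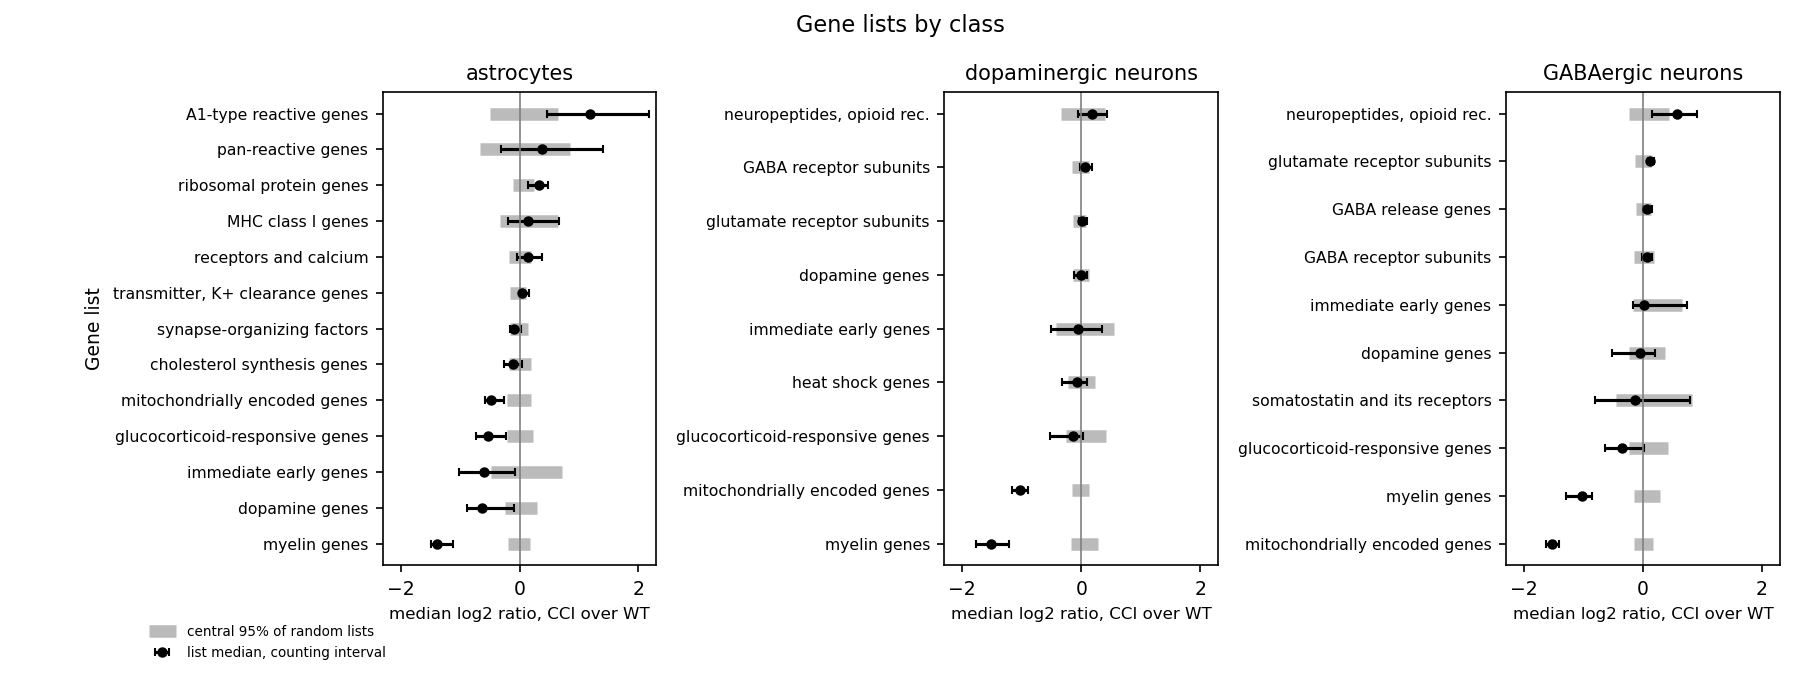
Median log2 ratio, CCI over WT, of each gene list described in astrocytes, dopaminergic neurons and GABAergic neurons (points, with bars for counting intervals), over the central 95% of matched random lists (grey). In astrocytes the glucocorticoid-responsive genes lay at -0.52 and the myelin genes at -1.38, and in dopaminergic neurons the dopamine genes lay at 0.00.

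The remaining classes were compared to describe the tissue around the cells of the title. In oligodendrocytes, Apoe and C4b were higher in the CCI library, as they were in astrocytes, and genes of cholesterol synthesis were lower. Apoe went from 35.3 to 126 CPM (1.83, 1.54 to 2.13) and C4b from 9 to 131 UMIs (2.53). The other complement genes went the other way: the list had a median of -1.10 (-1.49 to -0.48) at percentile 0.01, with 5 of 6 measured members over 1.5-fold lower and 1 higher, and the homeostatic microglia genes had one of -0.68 (-1.05 to -0.46) at percentile 0, with 7 of 10 lower. Ranked highest was Abca8a (ENSMUSG00000041828, chromosome 11, 110025634 to 110095978), a lipid transporter gene, at 2.79 (2.499 to 3.09), and the lipid droplet gene Plin4 (2.12) and Slc7a15 (1.94) were also higher. The 20 cholesterol synthesis genes had a median of -0.58 (-0.77 to -0.47) at percentile 0, with 10 over 1.5-fold lower and none higher: Hmgcs1, which makes the precursor of mevalonate, at -1.31, Idi1 at -1.17 and Msmo1 at -0.93. Heat shock genes had a median of -0.38, with 5 of 12 over 1.5-fold lower, among them Hspa1a (-1.71) and Hsph1 (-0.64).

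Ranked lowest in oligodendrocytes were the mannosidase gene Man1a (-1.83), the complement lectin pathway gene Masp1 (-2.01), the tissue plasminogen activator gene Plat (-1.90), Pcyox1l (-1.71) and Rtp4 (-1.75). Exons of Plin4, Man1a and Rtp4 overlap other genes. Myelin genes, the products of the class itself, had a median of -0.11 (-0.17 to -0.02) at percentile 3.06, with Cldn11 at -0.61 and Mobp at -0.49. Glucocorticoid-responsive genes had a median of 0.04, with Hif3a at 1.88 (1.51 to 2.28) and Sult1a1 at 1.56, and the nucleus-retained RNAs one of 0.07, with Neat1 at 1.22 (1.15 to 1.29) and Snhg11 at 0.31. Mitochondrially encoded genes had a median of -0.59, with mt-Nd6 at -1.49 and mt-Nd3 at -1.06, and dopamine genes one of -0.27, with Slc18a2 at -1.26 and Slc6a3 at -1.12. With equal weight per shared cluster Abca8a stood at 1.97, Slc7a15 at 0.63, Man1a at -0.42, Pcyox1l at -1.07 and the glucocorticoid list at -0.08, and thinning, which left 548 of 3888 WT nuclei, turned the dopamine list to 0.08 and moved Man1a to -2.85, Rtp4 to -2.78, Hif3a to 2.49 and Pcyox1l to -1.12; with at least 500 genes the list of nucleus-retained RNAs stood at 0.00.

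In oligodendrocyte precursors Apoe was higher as well (1.55, 1.16 to 1.96, from 60 and 467 UMIs), with Col11a2 (1.59), Lrp4 (1.53), Etv4 (1.34) and Mir9-3hg (0.77). Ranked lowest were Hmgcs1 (-1.13), Filip1l (-1.12), AY036118 (-1.05), Pwwp2a (-0.80) and Cbx5 (-0.78). Myelin genes had a median of -1.10, with Mobp at -1.95, cholesterol synthesis genes one of -0.25, with Insig1 at -1.23, and glucocorticoid-responsive genes one of -0.44, with Tsc22d3 at -1.56 and Sgk1 at -0.47. Mitochondrially encoded genes had a median of -0.32. Thinning, which left 124 of 544 WT nuclei, turned the glucocorticoid list to 0.39 and Insig1 to 0.13 (-1.83 to 2.62, from 3 and 10 UMIs). In the single precursor cluster shared by at least 20 nuclei of each library, Hmgcs1 turned to 0.23 and Mir9-3hg to -0.51, Tsc22d3 moved to -0.38, Col11a2 to 0.36 (from 12 and 2 UMIs) and Etv4 to 0.24 (from 26 and 4), and Insig1, with 22 WT UMIs and 0 CCI UMIs, gave no direction.

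In microglia, genes of antigen presentation and complement were higher in the CCI library, from a WT class of 167 nuclei at a median of 554 UMIs. The MHC class I genes had a median of 1.20 (0.25 to 1.91) at percentile 99.8 over 5 measured members, with H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347) at 1.45 (0.28 to 2.94) and B2m at 1.20 (0.23 to 2.37). Complement genes had a median of 0.72 (0.41 to 1.03) at percentile 99.98, with the C1q chain genes C1qb at 1.08, C1qc at 0.86 and C1qa at 0.83. These C1q genes were also among the markers that named the class. Homeostatic microglia genes were at 0.22 (percentile 92.4), with Tmem119 at 0.95 and the purine receptor gene P2ry12 at 0.51, and disease-associated genes at 0.36 (97.4), with the cathepsin genes Ctsb at 0.79 and Ctsd at 0.42. At the lower clustering resolution the medians moved to 1.19 for complement, 0.74 for homeostatic and 0.80 for disease-associated genes. Apoe stood at -0.45 (-1.52 to 0.79) in microglia, turning to 1.495 at the lower clustering resolution, and the disease-associated median turned to -0.03 when members with 5 UMIs were admitted. Single genes ranked highest were AU020206 (2.63), Ddi2 (1.97), Rap1a (1.35), Uvrag (1.31) and Tmcc3 (0.86), and ranked lowest were Dlg1 (-1.05), Ube2k (-1.04), Sdk1 (-1.003), Slc12a2 (-0.92) and AY036118 (-0.78). Exons of Ddi2 and Uvrag overlap other genes. Myelin genes had a median of -1.02 there, with Mobp at -1.59, and mitochondrially encoded genes one of -0.47.

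Over all neurons, the orexin gene Hcrt (ENSMUSG00000045471, chromosome 11, 100761069 to 100762931) ranked highest by the interval bound nearest to 0, with a ratio of 5.64 (4.28 to 7.52) and 4 UMIs in WT and 858 in CCI. A single subcluster of 13 WT and 323 CCI nuclei held 71.8% of the Hcrt UMIs of the CCI library. The vesicular glutamate transporter gene Slc17a8 was higher (3.60), as were Isl1 (3.44), Pax3 (6.01, 3.52 to 11.31, from 1 and 277 UMIs) and Vmn1r209, which had no WT UMI and was at least 9.28-fold higher. Neuropeptide and opioid receptor genes had a median of 0.33 (0.23 to 0.53) at percentile 99.6, with 8 of 20 over 1.5-fold higher and 2 lower, among them Gal (2.15) and Cartpt (1.61). Ranked lowest were AC160336.1 (-2.48), Ankk1 (-2.37), Frs3 (-1.85), the osteopontin gene Spp1 (-1.82) and Tll1 (-1.63). Dopaminergic transcripts were lower over all neurons, with Th at -1.14. Slc17a6, which marks glutamatergic neurons, stood at 0.51 (0.42 to 0.60), Gad2 at 0.09 and Sst at 1.39.

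The thinned share of all neurons with a Th UMI was 2.79% in WT and 1.12% in CCI, against 0.547% and 0.448% in oligodendrocytes. In astrocytes, which should lack Th too, the thinned share was also lower in CCI, at 1.45% in WT (3 of 207 nuclei) and 0.613% in CCI (9 of 1469). Without thinning the share of neurons was 5.22% and 6.34%. Thinning left out 1140 WT and 105 CCI neurons, and the neurons left had median depths of 1832 and 6322 UMIs before it. Myelin genes in neurons had a median of -1.14, with Mobp at -1.79, and mitochondrially encoded genes one of -1.34, with mt-Nd6 at -2.29 and mt-Nd4l at -1.99. With equal weight per shared cluster of neurons, Gal stood at 0.01, Cartpt at 2.94 (2.80 with equal weight per nucleus), Th at -0.46, Isl1 at 1.97, Vmn1r209 at 0.55 or more (0 WT and 42 CCI UMIs), Spp1 at -0.83, Tll1 at -0.98 and Ankk1 at -3.97, and thinning moved Ankk1 to -1.70 and Isl1 to 4.74 (2.84 to 7.81, from 2 WT UMIs). Pax3 and Vmn1r209 had no WT UMI after thinning and were at least 3.41 and 2.51.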

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

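Endothelial cells, pericytes and serotonergic neurons are described here because they had too few WT nuclei for a comparison of expression. Endothelial cells were 0.486% of the CCI nuclei (62) and 0.0574% of the WT nuclei (7). Pericytes were 0.345% of the CCI nuclei (44) and 0.0984% of the WT nuclei (12). The WT nuclei of endothelial cells and pericytes had median depths of 564 and 616 UMIs. These lie near the least number of 500 UMIs, which removed 690 WT barcodes and 0 CCI barcodes, so their WT shares may be lowered by the filter. Serotonergic neurons were 0.741% of the CCI neurons (49) and 0.201% of the WT neurons (12), and their subcluster was also led by Pmch and Hdc, so it may not be a pure serotonergic group.

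For 3 patterns, explanations were weighed with tests in the same data. The tests of a common source, of different tissue and of the mix of GABAergic subclusters were written down before their values were seen. The tests of myelin UMIs per nucleus, of oligodendrocytes alone, of depth, of a dopaminergic deficit alone and of free Sst RNA were chosen after the result had been seen. Those of myelin UMIs per nucleus and of depth replaced earlier tests that could not decide, after all values were known. The criterion for different tissue, the interval for the dopaminergic deficit, the comparisons with other classes, the restriction to neurons outside the dopaminergic class and the leaving out of subcluster 33 were settled after these values were seen. A biological effect of the injury could not be tested with 1 library per group.

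Myelin transcripts were lower in the CCI library outside oligodendrocytes. UMIs per nucleus of Mbp, Mobp, Mag, Mog and Cldn11 lay within 1.43-fold (1.36 to 1.82) over astrocytes, dopaminergic and GABAergic neurons, oligodendrocyte precursors and microglia of both libraries, at median depths from 554 to 9174 UMIs, and the makeup of myelin transcripts in WT astrocytes and WT neurons differed by 1.73 percentage points (0.820 to 3.49). Free oligodendrocyte RNA in a similar amount per nucleus, a smaller part of the deeper CCI nuclei, may therefore account for part of it. More free RNA per nucleus in WT does not, as the median ratio of these UMIs, WT over CCI, was 0.84 (0.755 to 0.93). Depth did not lower all foreign transcripts. Neuronal ones stood at -0.12 in astrocytes and 0.16 in oligodendrocytes, while dopaminergic ones in astrocytes stood at -1.43. Why myelin transcripts did not rise with depth as neuronal ones did was not tested. The makeup in WT astrocytes differed from that in WT oligodendrocytes by 13.2 points, so the source may not be whole oligodendrocytes, and within oligodendrocytes the median was only -0.11 (-0.17 to -0.02), too small for lower expression there to account for the rest. With equal weight per shared cluster the median was 0.00 in astrocytes, -0.58 in precursors and -0.82 in dopaminergic neurons, and because the astrocyte clusters split by library and depth the first value is left open.

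The share of dopaminergic neurons was lower in the CCI library. The summed CPM of Slc6a3, Slc18a2, Ddc and Th over all neurons was taken less the level in astrocytes or oligodendrocytes, per UMI or per nucleus. Under these 4 corrections it was at least 1.98 times higher in WT (1.81 to 2.15), so the depth gap alone does not account for the lower sum in CCI. The sum does not separate a lower share of these neurons from lower levels in each of them. An earlier test, the share of neurons with such a UMI at equal depth, was 1.89 times higher in WT (1.73 to 2.07). It could not decide because in astrocytes that share was 2.43 times higher (1.63 to 3.54). The summed CPM replaced it after all values were known, and the verdict on depth changed with it. Hypothalamic genes had a median of 1.21 (0.83 to 1.60) over all neurons, above all matched random lists. Of these genes, 10 of 15 were over 1.5-fold higher and 2 lower (Nkx2-2 at -1.45 and Pomc at -0.84). The median member was Nkx2-4, with 0 WT UMIs and 30 CCI UMIs, so 1.21 is a bound set by the floor. Hmx2 and Npvf also had 0 WT UMIs, and Trh, Oxt and Fezf1 had 1 each. Midbrain transcription factors had a median of -1.16 (-1.50 to -0.61) in neurons outside the dopaminergic class. En2 and Otx2, which dopaminergic neurons may express too, were left out of it. Of the other neuron subclusters, 65.4% (61.5 to 73.1) had shares that differed over 2-fold, but so did 9 of 10 clusters of astrocytes, oligodendrocytes, their precursors and microglia, so this count says little about a deficit of dopaminergic neurons alone. A dissection that took more hypothalamus in the CCI library may contribute to the lower share, while a deficit of dopaminergic neurons stays open.

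Sst was higher in the GABAergic neurons of the CCI library. Its CPM there was 6.86 times that in oligodendrocytes of the same library (5.58 to 8.49), so free RNA does not account for it. With equal weight per shared subcluster the ratio was -1.06 (-1.45 to -0.61). Without subcluster 33 (32 WT and 29 CCI nuclei, -2.97) it was -0.34 (-0.80 to 0.19), still below 1.36. The weighting left out subclusters 25 (0 WT and 134 CCI nuclei) and 29 (1 WT and 97 CCI nuclei), and with them CCI Sst UMIs but no WT ones. That favours a value below 1.36, so the weighting alone cannot decide. The higher level may still come from a different mix of GABAergic subclusters. Single subclusters went both ways, with subcluster 10 at -0.93 (-1.54 to -0.26), 12 at -0.31 (-1.22 to 0.77), 8 at 1.96 (0.71 to 3.485), and 24 with 0 WT and 15 CCI UMIs. Subclusters held mostly by 1 library may themselves stand for the library.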

How the results depend on the processing

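Of 3288 alternative values for 235 gene ratios, 2963 stayed the same, 296 moved and 29 reversed, 3 of these at the floor of 3 counts. Of 786 for 50 list medians, 722 stayed, 55 moved and 9 reversed, and of 92 for 15 shares, 66 stayed, 20 moved and 6 reversed. TMM scaling and the total without mitochondrial, ribosomal protein and haemoglobin genes and Malat1 moved 0 of the 235 genes. Values below are log2 ratios, and the cause of each was not tested unless stated.

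Equal weight per shared cluster, chosen after seeing the data, moved 88 genes and reversed 16. In astrocytes it gave Apoe 0.93, Ephb1 0.10, Fkbp5 0.0777, Mbp 0.12, Slc1a2 -0.17, Slc7a11 -0.37, mt-Nd6 0.25, and medians of -0.15 for clearance genes, 1.04 for mitochondrially encoded genes and 0.0024 for myelin genes. In dopaminergic neurons it gave Ddc -0.12, Grin2a -0.36 and the dopamine list -0.37. In GABAergic neurons it gave Eepd1 -0.82 (main value 2.31), Grik1 -0.39, Grik3 -0.28, Pax5 0.0629 (main value -1.31) and Sst -1.06, or -0.34 without subcluster 33. In oligodendrocyte precursors, where a single cluster of 539 WT and 21 CCI nuclei was shared, it gave Hmgcs1 0.23 and Mir9-3hg -0.51. Insig1 had 22 WT UMIs and 0 CCI UMIs there, so its value of 0.0691 is set by the floor and gives no direction.

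Thinning to 1000 UMIs moved 64 of 212 genes and reversed 6. In astrocytes it gave Apoe 1.44, Slc7a11 -0.0258, the clearance list -0.0322 and the A1-type list 0.065, with 1 of its 4 members at the floor, and the pan-reactive list was -0.71 with 2 of 4 there. In dopaminergic neurons it gave Ddc -0.0266, Mid1 -0.24 and the dopamine list -0.13. In GABAergic neurons Fosl2 and Npas4 had 0 WT UMIs and 4 CCI UMIs each after thinning, so their values of -0.0768 and -0.0768 are set by the floor and give no direction. In oligodendrocyte precursors it gave Insig1 0.13 (-1.83 to 2.62, from 3 and 10 UMIs) and the glucocorticoid list 0.39, and in oligodendrocytes the dopamine list 0.0825, with 2 of its 19 members at the floor. For GABAergic neurons with an Sst UMI the ratio was 2.22 thinned to 2000 UMIs and 2.35 without thinning, and for neurons with a Th UMI 0.28 without thinning, where the deeper library detects more by construction.

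Gating neurons by transcripts gave a dopaminergic share of -0.0672, Ddc -0.68, Grin2a -0.0891, the dopamine list -0.83, the neuropeptide and opioid receptor list 1.09 and the GABA receptor list 0.55 in dopaminergic neurons. In GABAergic neurons it gave a share of 1.84, Gad2 -0.98, Slc32a1 -0.83, Tmem132cos 0.0899 (main value -1.30) and the release list -0.0111.

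The share of GABAergic neurons, 0.18 in the report, was -0.0387 with at most 10% mitochondrial UMIs, 0.47 with doublets kept, 0.60 at the lower resolution, 0.92 with each library clustered alone and 1.05 without scaling within a library. With naming rules chosen after seeing the data it was -0.31 at a marker level of 0.15 and -0.0121 with leading genes against all other clusters. Its direction is therefore not settled. Sst in GABAergic neurons was 1.75 at the lower resolution, 2.51 with each library alone, 0.86 without scaling and 2.01 at a level of 0.2, and Fosl2 was -0.38 at a level of 0.15.

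With at least 500 genes the shares were 0.33 for astrocytes, -1.02 for dopaminergic neurons, -0.20 for neurons, 0.29 for oligodendrocytes and 2.52 for microglia (49 WT nuclei), and the nucleus-retained RNAs in oligodendrocytes stood at -0.0014. The neuron share was 0.27 at the higher resolution, and the oligodendrocyte share -0.48 with leading genes against all other clusters. The disease-associated list in microglia was -0.033 with members of at least 5 UMIs.

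The WT library was shallower, which limits genes with few WT UMIs and left 207 WT astrocytes at 1000 UMIs. Expression in microglia gave no value with at least 500 genes (49 WT nuclei) or thinned (5), against a least number of 50. No paired analysis was possible because each group was 1 library, and counting intervals do not cover differences between animals or dissections.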

Other observations

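Some genes differed in the same direction in several classes. Apoe was higher in the CCI library in astrocytes (1.24), oligodendrocytes (1.83) and oligodendrocyte precursors (1.55), and C4b in astrocytes (3.06) and oligodendrocytes (2.53). In microglia Apoe stood at -0.45 (-1.52 to 0.79), or at 1.495 (0.79 to 2.28) at the lower clustering resolution. Pcyox1l was lower in astrocytes (-1.47), GABAergic neurons (-1.57) and oligodendrocytes (-1.71). In oligodendrocytes Ddc was higher, from 62.7 to 117 CPM (0.90, 0.67 to 1.13), while Slc6a3 was at -1.12 and Slc18a2 at -1.26; Ddc was picked out there after its value had been seen.

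Among peptide genes of neurons, picked out after their values were seen, Pmch, which encodes melanin-concentrating hormone, had 150 UMIs in WT and 2942 in CCI, with 62.0% and 64.0% of them in the subcluster named serotonergic. Trh had 1 and 110 UMIs and Oxt 1 and 60. Agrp, a feeding peptide gene whose exons overlap Gm5914 and Ctcf, was level at 52.6 and 50.5 CPM (-0.06). Summed haemoglobin transcripts in neurons were higher in the CCI library (1.83, 1.40 to 2.29).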
